A study of Arabidopsis thaliana with 6 samples.

How the data were processed

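Leaves of 3-week-old Arabidopsis thaliana plants of the Col-0 accession were infiltrated with an artificial diet of sucrose and amino acids, either diet on which green peach aphids (Myzus persicae) had fed or diet kept without aphids. Per the labels' protocols, 50 aphids were offered 50 µL of diet for 24 h, and diet from 20 aphids or from cups with 0 aphids was collected and pushed into attached leaves with a needleless syringe. Each sample pooled 18 leaves, 3 from each of 6 plants, taken 24 h after treatment. Per the labels' protocols, both kinds of plant shared pots so that they could be compared as pairs, and the experiment was done 3 times, which gave 3 control and 3 saliva samples. Each sample was hybridised to 1 Affymetrix ATH1 GeneChip, a 1-colour array on which a gene is read by a probe set of short oligonucleotides.

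The authors deposited normalized intensity values on a linear scale, 1 per probe set and array. GCRMA, GCOS and limma are named in the submitters' processing notes, with versions, roles and order not given in the sources used here. The 2 deposited tables held 15236 probe sets and differed in 0 cells of the array values, so a second set of values was not used as an alternative. The authors also deposited a fold change, which was a ratio of the linear group means to within 0.173% for each probe set, and 2 columns of false discovery rates (adjusted p-values), named paired and unpaired per the file headers. Of the probe sets, 59 were Affymetrix controls and 15177 were tested. The number of columns of per-sample values left unused was 0.

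Log2 values were taken here without a pseudocount, since each deposited intensity was above 0. Arrays have no read depth, and their number limits the precision. The lowest intensity on an array lay between 3.23 and 3.28 and the median between 139.2 and 146.8. The largest share of equal values between 2 arrays was 2.11%, so no array was a copy of another.

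The probe annotation used here gave 1 gene for 8330 probe sets, several genes for 334 and no gene for 6513. Symbols were updated through the gene number in the RefSeq table of assembly TAIR10.1, where 8298 of the 8330 were found. Probe sets with several genes or with no gene in these tables were tested but not named. The sources used here gave no genome build for the arrays, so genes are identified by locus and no coordinates are printed. A gene with several probe sets was represented by the one with the highest mean, which left 8230 genes.

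Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the replicate number as a block, and p-values were adjusted by the Benjamini-Hochberg method over the 15177 probe sets, with a threshold of 0.05. The block follows the shared pots and repeats described in the labels' protocols. As a check, deviations from the group mean were correlated across probe sets between the samples of a pair, with values of -0.12, 0.15 and 0.10 for pairs 1, 2 and 3. Probe sets are not independent replicates. The raw file names in the labels separate replicate 1 from replicates 2 and 3, so a fit with that grouping as a block was added, and the fit without replicate 1 is the value within the larger batch. The other batch holds 1 pair and gives no test.

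Gene lists were fixed before the data were examined, 23 lists with 316 loci, of which 37 loci had a named probe set of their own. The 6 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation and fry as alternatives. Of the fixed members, 3 of 25 were measured for jasmonate, 3 of 20 for abscisic acid and 3 of 10 for auxin response. For photosynthesis 5 of 26 were measured, for pattern-triggered immunity 7 of 24 and for touch, wounding and calcium 3 of 10. A list mean therefore describes the measured members and not the whole list. Measured here means having a named probe set of its own. Other members may have been tested among the probe sets without a gene name, so they are not shown to be absent from the array. The rule for named genes was also fixed before the data were examined. It took up to 12 genes per direction among probe sets past the threshold that moved the same way in all 3 pairs. Where fewer passed, it filled the direction to 10 with the smallest p among probe sets of 1 gene that moved the same way in all 3 pairs. It added up to 3 members of each list with the smallest p, and a set of defence genes of which PDF1.2 was the 1 measured under its own name here. RNA integrity was compared as the log2 difference between 3′ and 5′ probe sets, in 6 readings of the actin, GAPDH and ubiquitin control transcripts. An exact paired sign-flip permutation test was used.

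Alternatives fixed before the data were examined were a fit without the block, a floor at a mean log2 value of 4, an intensity trend in eBayes, quantile normalization, median centring, array weights, each pair left out, and other thresholds. Fits with an estimated block correlation, with a block correlation fixed at 0.75, with the array batch as a block and with the control probe sets kept were added after the data were seen.

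The fits were tested on simulated data for this comparison, with the real probe sets' means, spreads drawn from the variance prior that limma fitted, and 200 of 15177 probe sets changed, over 10 simulations. The paired fit recovered 0.299% of changes of 1.5-fold, 36.6% of changes of 2-fold and 83.0% of changes of 4-fold, with 4.7 false calls on average. Without the block these shares were 39.7%, 74.6% and 93.9%. The simulated arrays shared no effect within a pair, so the block could only cost precision by construction. These shares therefore do not rank the fits for the real arrays. Camera called a simulated list of 10 independently drawn genes, each raised 2-fold, in 10 of 10 simulations at an unadjusted p under 0.05. It called an unchanged list in 1 of 10. The real lists had 3 to 7 measured members, smaller mean differences and an adjusted threshold, so these shares do not give the power for them. Figures were drawn with matplotlib 3.10.9.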

Results

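The series asks which Arabidopsis leaf transcripts differ 24 h after infiltration of diet that carried green peach aphid saliva, against diet without it. Normalized intensities of 15177 probe sets were compared between 3 saliva and 3 control arrays, paired by repeat. The median intensity per array lay between 139.2 and 146.8, so the arrays were on a like scale.

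The genes with the smallest p on the saliva side had log2 differences, saliva minus control, between 0.66 and 1.76. AT4G22470, of the protease inhibitor, seed storage and lipid transfer protein family, had a difference of 1.76 ± 0.30 (SD, n = 3 pairs), from a mean log2 intensity of 4.54 in controls to 6.30 after saliva. AT3G49340, a cysteine protease of the papain type, had 1.47 ± 0.36, and AT1G62510, another member of the lipid transfer protein family, had 0.99 ± 0.17. AT2G38870, a potato type I serine protease inhibitor, had 0.90 ± 0.16 at a high control level of 9.32. On the control side, AT1G23205, of the invertase and pectin methylesterase inhibitor family, had -1.06 ± 0.14, and the class III peroxidase AT5G51890 had -1.05 ± 0.21.

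None of these genes passed the test. In the paired limma fit 0 probe sets were higher and 0 were lower at an adjusted p under 0.05, and the lowest adjusted p was 0.338. At an unadjusted p under 0.05 there were 1674 probe sets, 848 higher and 826 lower, where 758.9 are expected by chance. Without replicate 2 that count was 941, and with array weights, which gave pair 2 the most weight, it was 2723. After quantile normalization 751 were higher and 966 lower, and after median centring 776 and 990. The limma fit without the block also called 0 probe sets, with 1760 at an unadjusted p under 0.05. Its lowest adjusted p was 0.078, and 2 probe sets had an adjusted p under 0.1, those of AT5G22460 and AT4G15830. Differences had the same direction in all 3 pairs for 4898 probe sets, 32.3%, against 25% by chance.

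Other genes named on the saliva side were AT5G22460 with 0.91 ± 0.094, AT3G23550, a MATE transporter, with 0.80 ± 0.15, and AT2G17740 with 0.75 ± 0.043. AT2G07777 had 0.68 ± 0.070 and AT1G05340 had 0.68 ± 0.076. XTH33, a xyloglucan endotransglucosylase/hydrolase that remodels cell walls, had 0.66 ± 0.054, from a dim control level of 2.80. On the control side AT5G01015 had -0.93 ± 0.28, MYR2, a MYB-related transcription factor, had -0.85 ± 0.15, AT5G20030 had -0.84 ± 0.24 and AT4G15830 had -0.82 ± 0.031. AT3G62820, of the same inhibitor family as AT1G23205, had -0.73 ± 0.11, and AT2G40480 had -0.62 ± 0.055. CRR41, needed for the chloroplast NADH dehydrogenase-like complex, had -0.58 ± 0.10, and AT3G08740, an elongation factor P family gene, had -0.57 ± 0.050. These 20 genes were picked for a small p, which by itself favours genes with a small spread between pairs. Of them, XTH33, AT2G07777, AT5G20030 and AT4G15830 drop out with the floor at a mean log2 value of 4. Their control levels were 2.80, 3.44, 4.05 and 4.28.

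**Figure D1:**
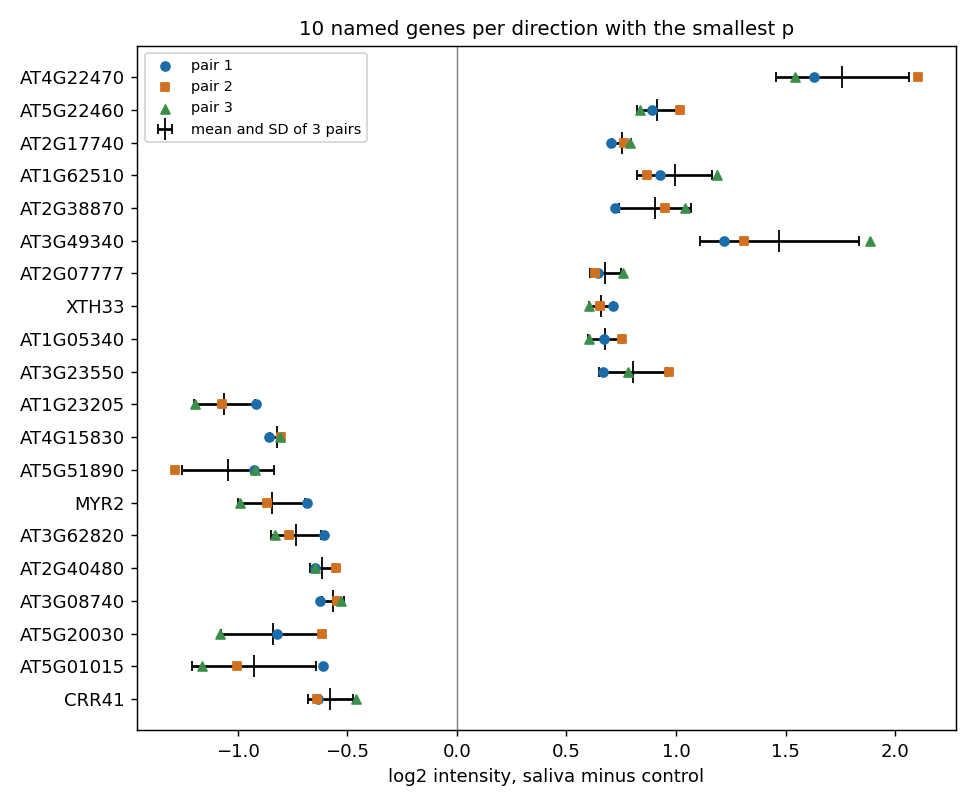
Log2 intensity difference, saliva minus control, for the 10 named genes per direction with the smallest p. Symbols are the 3 pairs and bars are the mean and SD over pairs, and AT4G22470 has the largest mean, 1.76, while none of these genes passed the adjusted threshold.

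The authors' deposited table lists 463 probe sets with a paired rate under 0.05, 214 with a fold above 1 and 249 below 1, and 0 with an unpaired rate under 0.05. Of the 463 in the authors' deposited table, 31 had a fold of at least 2 in either direction. Among its called genes, chosen here after their values were seen, log2 differences in the limma fit were 1.86 ± 0.80 for AT1G50040, 1.54 ± 0.46 for AT1G80130, 1.46 ± 0.54 for AT5G52390, 1.33 ± 0.59 for AT4G27450 and 1.28 ± 0.56 for EXO, a brassinosteroid-responsive gene of cell expansion (SD over 3 pairs), beside AT4G22470 above. Lower ones were -1.43 ± 0.58 for AT1G60590 and -1.13 ± 0.49 for AT1G63310. Control levels of AT1G50040 and AT1G63310 were low, at mean log2 values of 3.62 and 4.01. Each of the 463 probe sets moved the same way in all 3 pairs and had an unadjusted p under 0.05 in the paired fit, and 0 passed its adjusted threshold. The extreme folds of the authors' deposited table rest on 1 array each. The highest, 40.5, came from 815.8 on the saliva 3 array against 5.49 to 8.45 on the others, and the lowest, 0.0597 for AT5G26270, came from 294.97 on the control 2 array against 6.08 to 6.2 on the others.

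Auxin response genes had a list mean of 0.70, with pair means of 0.57, 0.78 and 0.75. WES1 and GH3.3, which conjugate auxin to amino acids, had 1.33 ± 0.86 and 0.71 ± 0.43, both from control levels of 2.51 and 2.60 near the lowest intensities, while IAA29 had 0.061 ± 0.92. The list did not pass the test (camera adjusted p = 0.053, and adjusted p = 0.416 with an estimated correlation). Of its 3 measured members 0 passed when adjusted over all probe sets and 2, WES1 and GH3.3, when adjusted over the list alone. With a floor at a mean log2 value of 4 those 2 members drop out and the list could not be tested.

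Abscisic acid and water stress genes had a mean of 0.34, with pair means of 0.55, 0.11 and 0.35. The dehydrin COR47 had 0.62 ± 0.071 at a high control level of 12.04, COR15A had 0.22 ± 0.40 and LTI30 had 0.18 ± 0.40. The camera adjusted p was 0.053, and the adjusted p was 0.416 with an estimated correlation. When adjusted over the list alone, 1 of the 3 members passed, COR47. These 2 lists were called under some alternative settings and not under others.

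Jasmonate synthesis and response genes had a mean of 0.23, with pair means of 0.086, 0.10 and 0.49 (camera adjusted p = 0.194). THI2.1, a thionin, had 0.68 ± 0.35, from a control level of 2.87 near the lowest intensities. PDF1.2, a plant defensin, had 0.20 ± 0.030, and JMT, jasmonate methyltransferase, had -0.21 ± 0.38. Of the 3, 1 passed when adjusted over the list alone, THI2.1. With a floor at a mean log2 value of 4 THI2.1 drops out and the jasmonate list could not be tested. Photosynthesis genes had a mean of -0.066, with pair means of -0.028, -0.059 and -0.11 (camera adjusted p = 0.244), with -0.15 ± 0.057 for PSAN, -0.091 ± 0.019 for PSBW and -0.070 ± 0.022 for LHCB4.1. Pattern-triggered immunity genes had a mean of 0.088 over 7 members, with pair means of 0.21, -0.11 and 0.16 (camera adjusted p = 0.435), with 0.24 ± 0.25 for BIK1, 0.24 ± 0.42 for WRKY53 and -0.20 ± 0.31 for EFR. Touch, wounding and calcium genes had a mean of 0.067 (camera adjusted p = 0.658), whose sign rests on pair 1, with pair means of 0.62, -0.24 and -0.18. Its members went both ways, with -0.49 ± 0.67 for STZ, 0.45 ± 0.70 for CML38 and 0.25 ± 0.47 for CML37. In these last 3 lists 0 members passed when adjusted over the list alone.

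**Figure D2:**
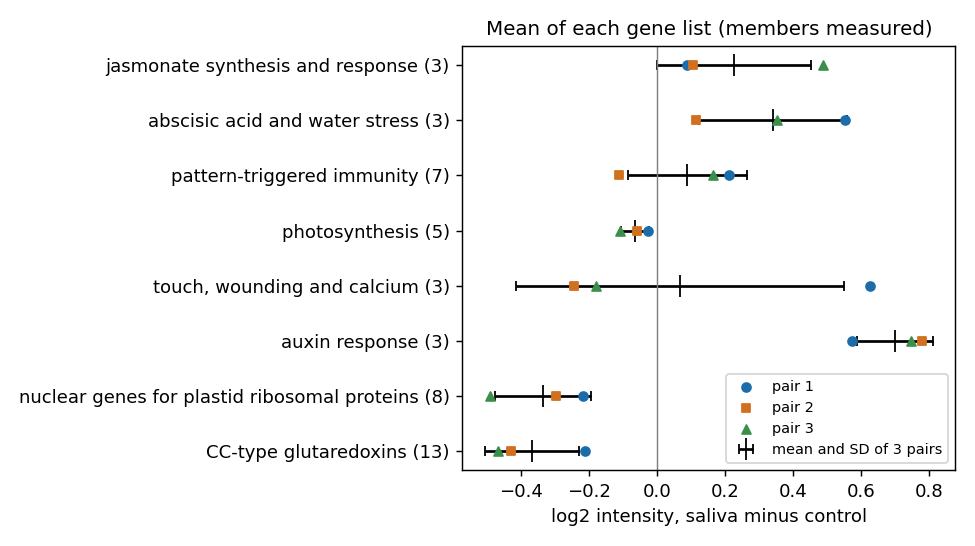
Mean log2 intensity difference, saliva minus control, of the 6 gene lists tested and of 2 lists added after the data were seen (the bottom 2), with the number of members measured. Symbols are the 3 pairs and bars are the mean and SD over pairs, and the auxin response list has pair means of 0.57, 0.78 and 0.75.

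Another 11 lists had 1 or 2 measured members, that is, members with a named probe set, and were not tested as lists. Their other members may be among the probe sets tested without a gene name. APL3, a large subunit of the starch synthesis enzyme ADP-glucose pyrophosphorylase and the 1 measured member of the sugar and amino acid transport list, had 0.65 ± 0.094 (limma adjusted p = 0.338 over all probe sets). In the salicylic acid defence list SAG101 had 0.28 ± 0.35 and GRX480 had 0.16 ± 0.48. EIN3 of the ethylene list had 0.18 ± 0.15. In the aliphatic glucosinolate list AT2G31790, listed as UGT74C1, had -0.37 ± 0.26 and BCAT4 had -0.046 ± 0.25. UGT74B1 of the indole glucosinolate list had -0.068 ± 0.18. In the flavonoid list DFR had 0.35 ± 0.63, which rests on pair 3 with 1.08, and WRKY6 of the senescence list had 0.22 ± 0.33. AT2G21640 of the oxidative stress list had -0.023 ± 0.23, and the clock gene GI had -0.089 ± 0.059. BIK1, given above, was the 1 measured member of the aphid resistance list. The reference genes AT4G34270 and AT2G28390 had 0.17 ± 0.29 and 0.070 ± 0.18. The camalexin, heat shock, phloem, xylem, epidermis and meristem lists had 0 members with a named probe set of their own and were not analysed here.

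RNA integrity showed no difference between the groups beyond the spread between pairs. The 3′ minus 5′ log2 difference was averaged over 6 readings of the actin, GAPDH and ubiquitin controls, each read more than once. This average differed between saliva and control by -0.013, 0.11 and -0.012 in pairs 1, 2 and 3 (exact two-sided paired permutation p = 1). Readings of 1 transcript could disagree, as those of GAPDH in pair 1 differed by -0.27 and 0.26, so an average near 0 can hide opposite readings. The smallest p that 3 pairs can give is 0.25. The 25S ribosomal RNA control had differences of 0.68, 0.19 and 0.024 in the same pairs.

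**Figure D3:**
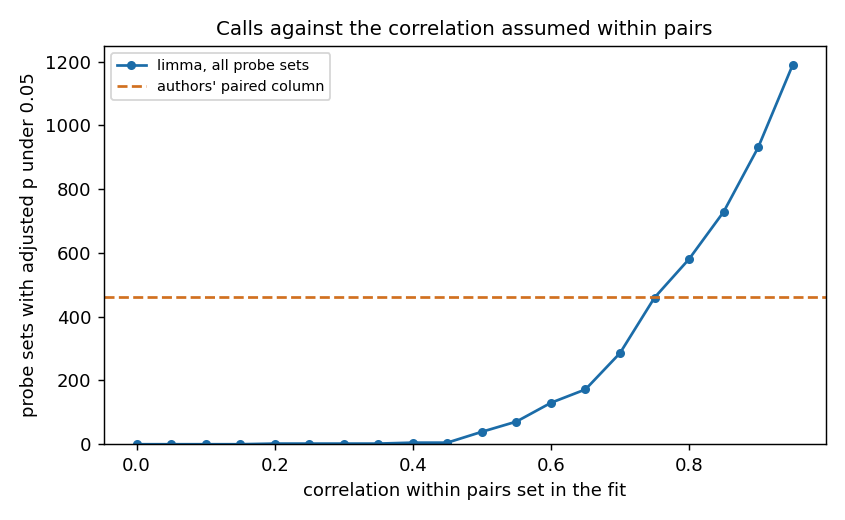
Number of probe sets with an adjusted p under 0.05 (vertical axis) in limma fits that set the correlation within pairs to the value on the horizontal axis, with all 15236 probe sets. The dashed line is the 463 probe sets of the authors' paired column, and the curve has 0 at a correlation of 0, 39 at 0.5 and 460 at 0.75.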

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

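The counts of higher and lower probe sets both stayed at 0 without the block (no replicate block: 0 and 0). They did so with the mean log2 floor, intensity trend, quantile normalization, median centring, array weights and each pair left out. In the paired fit they were 0 at an adjusted p under 0.1 and at an adjusted p under 0.05 with 2-fold. They also stayed at 0 with an estimated block correlation, the array batch as a block and the control probe sets kept, all added after the data were seen. With a block correlation fixed at 0.75, also added then, 221 were higher and 255 lower. At an unadjusted p under 0.05 with at least 2-fold, 70 were higher and 14 lower, a looser threshold by construction. Gene lists past the threshold went from 0 to 1 with fry (auxin response), 1 with the mean log2 floor (abscisic acid and water stress; the floor left 3 of the 6 lists to test and adjust over, without auxin response), 2 with median centring (both of these) and between 0 and 2 with a pair left out (0 without replicate 1, 2 without replicate 2, 1 without replicate 3); the cause was not tested. It stayed at 0 with an estimated correlation (adjusted p = 0.416 for both lists), without the block, with quantile normalization and with the mean of all probe sets of a gene. Among 51 named genes, 22 passed with the correlation fixed at 0.75 and in no other fit. The array weights were equal within each pair, at 0.62, 2.22 and 0.72 for pairs 1, 2 and 3, so that fit leans on pair 2. Array weights turned 3 of these genes, GRX480 to -0.074, BCAT4 to 0.059 and AT2G21640 to 0.058, and moved 13 by over 1.5 times without a turn, such as COR15A to 0.020, LTI30 to 0.062, WRKY53 to 0.088 and CML38 to 0.098. Quantile normalization moved 4 so, such as BCAT4 to -0.0050, and median centring moved 1, AT2G21640, to -0.038. Leaving out a pair moved 23 named genes by over 1.5 times or across 0, none of them among the 20 with the smallest p. Of these 15 kept their sign, such as WRKY53, at 0.011 without replicate 1, GH3.3, at 0.46 without replicate 3, STZ, from -0.87 to -0.23, and CML38, from 0.20 to 0.84; the others were SAG101, JMT, EIN3, COR15A, AT2G31790, BIK1, EFR, WRKY6, GI, CML37 and AT4G34270. The other 8 turned, with ranges of -0.034 to 0.43 for GRX480, -0.053 to 0.29 for LTI30, -0.16 to 0.087 for BCAT4, -0.12 to 0.038 for UGT74B1, -0.12 to 0.11 for AT2G21640, -0.014 to 0.54 for DFR, -0.34 to 0.56 for IAA29 and -0.026 to 0.15 for AT2G28390; the cause was not tested. The other deposited table held identical values and was not run. Dim probe sets limit fold changes near the lowest intensities.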

Other observations

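The tests of added gene lists, of the authors' paired column, of the splits and of the saliva replicate 3 array were chosen after the results were seen. Of 37 listed nuclear genes for plastid ribosomal proteins 8 were measured, and each of these 8 was below 0 in all 3 pairs. The list mean was -0.34, with pair means of -0.22, -0.30 and -0.49. AT1G29070 had -0.51 ± 0.093 (SD, n = 3 pairs) and AT5G65220 had -0.15 ± 0.135. Camera gave p = 1.06e-06 at the preset correlation, p = 0.132 with an estimated correlation, and fry gave p = 0.0439. The list mean was -0.32 after quantile normalization and -0.35 after median centring. Chloroplast-encoded genes had a mean of -0.10 over 69 genes, with pair means of -0.19, -0.16 and 0.030 (camera p = 0.000537, p = 0.388 with an estimated correlation). Cytosolic ribosomal protein genes had pair means of 0.098, -0.097 and -0.32 over 38 members (camera p = 0.00109, p = 0.528 with an estimated correlation).

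CC-type glutaredoxins, small plant redox proteins, were below 0 in all 3 pairs for 9 of 13 measured genes, with a list mean of -0.37. AT1G06830 had -1.06 ± 0.37 and AT2G47880 had -0.91 ± 0.46, while GRX480 had 0.16 ± 0.48. Camera gave p = 1.54e-05, p = 0.0873 with an estimated correlation, and fry gave p = 0.0353. Near-identical tandem copies on chromosome 4 may share signal. Of the 9 members outside them, 5 lay below 0 in all 3 pairs and the other members had means above 0. Their pair means were -0.15, -0.43 and -0.41, over members from -0.67 to 0.56 in pair 1 (camera p = 0.0115, p = 0.119 with an estimated correlation, fry p = 0.0694). Signal shared between the tandem copies stays open, since these means lie within the spread over members. The pair means of the whole list were -0.21, -0.43 and -0.47, also within that spread. Pair 2 was close to pair 3, and 9 of 13 members were below 0 in all 3 pairs, so the fall was not confined to replicate 3. The list was noticed in these same pairs, so they cannot test whether it would recur. In 1 of the 10 splits of the 6 arrays, the real one, the camera p was as small, and the smallest p of the others was 0.00391, in a split that parts 1 pair. The other splits that part all 3 pairs gave 0.0531, 0.294 and 0.838. The 10 splits make 7 distinct blocked fits, too few for a share under 0.05. A response to saliva remains a hypothesis, since the list was noticed in these data.

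The authors' paired column calls 463 probe sets where the paired limma fit calls 0. A limma fit with a block correlation fixed at 0.75 over all 15236 probe sets gives 460 calls, each of them among the 463, and its rates differ from the deposited ones by at most 0.0237. Of the correlations scanned, 0.75 came closest to the deposited rates, with largest differences of 0.0508 at 0.7 and 0.0603 at 0.8. The match is therefore to a best-fitting value and not to one set in advance. With the pairs as a fixed block the largest difference is 0.473. Leaving out the control probe sets does not account for the gap, because the paired fit with them kept has 0 calls. The consensus correlation estimated from these arrays was -0.054, so a correlation set above that estimate is a candidate explanation of the 463 calls. How the authors obtained their column is not given in the sources used here.

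The fit with the fixed correlation called 476 of the 15177 probe sets with all pairs, and 0 without replicate 1, 0 without replicate 2 and 0 without replicate 3, where 4 arrays remain in each fit. On simulated arrays with no effect and no correlation within pairs it gave 2.5 calls on average and 8 at most, with 13.5% of p-values under 0.05. Where 200 simulated probe sets changed, it made 86.7 false calls on average, against 4.7 in the paired fit and 8 in the fit without pairs. Pair differences correlated across probe sets at 0.22 for pairs 1 and 2, 0.13 for pairs 1 and 3 and 0.42 for pairs 2 and 3, and probe sets are not independent replicates. Of the 10 splits of the arrays, 1 gave as many calls with the fixed correlation, with 476 in the real split and 0 as the highest other. At an unadjusted p under 0.05, 1 of the 10 gave as many, with 1674 in the real split and 1563 as the highest other. That other split parts 1 pair, so its blocked fit rests on 1 pair difference. Apart from the real one, the splits that part all 3 pairs had 817 at most. For the adjusted counts the real value was 0, which 10 of 10 splits reach by construction, so these say nothing about chance; the highest values among the other splits were 6 probe sets and 2 gene lists, in different splits. With 10 splits no share can be under 0.05.

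The saliva replicate 3 array held 19 probe sets more than 2 log2 units above the mean of the other 5 arrays, whose range was under 1, against 2 on the control 2 array and 0 on each of the others. Named ones include OSM34, an osmotin-like protein, at 6.49 against 2.17, JRG21, a jasmonate-regulated gene, at 8.49 against 6.07, and BGLU45, a beta-glucosidase, at 6.96 against 2.78. In pairs 1 and 2 JRG21 differed by 0.81 and 0.56, but OSM34 by -0.038 and 0.0064 and BGLU45 by -0.010 and 0.040. The median of the saliva replicate 3 array differed from that of the others by -0.046 on the log2 scale. The deposited values are already normalized between arrays, so this says nothing about the brightness of the scan, which stays open. Another tissue in that sample stays open, since 0 of the listed markers of other tissues were measured under a gene name here. A larger response to saliva in replicate 3 may contribute, as 10 of the 19 were also higher after saliva in both other pairs, against 28.1% of all probe sets as steady on the other arrays (exact binomial p = 0.0205, one-sided, with probe sets that are not independent and mostly near the lowest intensities). Limited to the 4 whose mean on the other arrays was at least 4, the count was 4, against 31.2% (exact binomial p = 0.00942, one-sided).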
